A study of Homo sapiens with 24 samples.

How the data were processed

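Gene expression was measured by RNA sequencing of total RNA (TRIzol) from 24 libraries of 2 cell lines, prepared as TruSeq mRNA libraries and read as pairs on a NovaSeq instrument, per the labels' protocols. The deposited values are raw counts per Ensembl gene, 1 table per cell line, made by the authors without normalization. Per the submitters' processing notes, reads were trimmed with fastp 1.3.2, aligned to GRCh38 with HISAT2 2.2.2 and assigned to genes with featureCounts of Subread 2.1.1, with bcl2fastq, MultiQC 1.33, R 4.4.1 and DESeq2 1.42.1 also named. The annotation release, the strand option and the handling of reads that map to several genes are not given in the sources used here, so reads of overlapping antisense genes and of close paralogs can be counted together. For 4 OCUG-1 libraries extra sequencing runs were pooled as technical replicates per the labels, which do not say which libraries they were. All values were whole numbers of at least 0.

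Each table held 78724 gene IDs, of which 61481 matched the gene name table, 42179 had a symbol and 57302 were in GENCODE release 29, the source of coordinates, biotypes, transcript length and GC content. Libraries were grouped by cell line and arm as the labels state, with 3 per group. Replicate numbers are not stated to pair libraries across arms and were not used as pairs. With group means removed, 6 of 12 HuCCT1 and 3 of 12 OCUG-1 libraries correlated best with a library of their own number. Same-number pairs had a median correlation of 0.0505 in HuCCT1 (highest 0.396) and -0.0295 in OCUG-1 (highest 0.244). Other pairs had medians of -0.0236 and 0.00972. The total count per library ran from 14388855 to 30693736. Counting error is small at this depth next to the spread between replicates: over 24 pairs of replicates, the chi-square per degree of freedom against counting error alone was 4.89 to 59.0.

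Genes were tested with edgeR 4.0.16 in R 4.3.3: trimmed mean of M values (TMM) scaling, the filterByExpr filter with a minimum count of 10, and quasi-likelihood F tests with robust dispersion, in 1 fit of 12 libraries per line and 1 fit of 24 libraries for differences between lines. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Standard errors of log2 fold changes were derived from the F statistic. CPM values (counts per library total, scaled per-million) are means with SD over 3 libraries, scaled by the TMM factors. Gene lists were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, for lists with at least 5 tested genes. Camera compares a list with all other genes, and calls were recomputed with a correlation estimated per list. The count adjusted over the list alone applies the Benjamini-Hochberg method to the members' p-values only.

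The comparisons, tests, named-gene rule, 31 gene lists and most alternatives were chosen before the data were examined. The lists cover oxidative phosphorylation (complex I, complexes II to IV, ATP synthase and their union), mRNAs from mitochondrial DNA, the mitochondrial ribosome, biogenesis regulators, the TCA cycle, glycolysis, hypoxia, fatty acid oxidation and synthesis, cholesterol, the integrated stress response, the ER unfolded protein response, mitochondrial chaperones, MAPK output, mitosis, DNA replication, p53, NRF2, autophagy, interferon, NF-kB, sorafenib target kinases, and biliary, mesenchymal, hepatocyte, fibroblast, immune and endothelial markers. Genes named by rank are the 5 largest rises and 5 largest falls per main comparison (3 and 3 for the direct dose comparison, the combination against vehicle and the lines without drug) among called protein-coding genes with a symbol, a mean of at least 10 CPM in the higher group and all 3 libraries of a group above all 3 of the other. For differences between lines the rule took 5 and 5 without the last condition. Up to 4 members with the smallest adjusted p were eligible per called list, together with a fixed panel of 16 genes, and the text names a selection of these. Not every eligible gene is given a value, and genes whose call ended under an alternative were mostly left out as examples.

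The edgeR and camera steps were tested on simulated data with 4 simulations of 200 changed genes. In the HuCCT1 design edgeR recovered 28.7% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 88.6% of those changed 4-fold, with 6.65% false calls. In the OCUG-1 design the values were 29.5%, 60.1% and 86.0%, with 3.91% false calls, and for the difference between lines they were 7.09%, 32.8% and 58.3%, with 7.45% false calls. Changed lists were called in 4 of 4 simulations and unchanged lists in 0 of 120 tests in each design. Genes were simulated independently of each other, so these tests do not measure false list calls where genes move together. The 200 changed genes were also far fewer than the genes called in any real comparison. Principal components used log CPM with a prior count of 2. Overlaps of comparisons that share libraries were set beside 20 simulated sets of unchanged groups.

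Alternatives were the DESeq2 1.42.0 Wald test, median-of-ratios (RLE) factors, library size alone, no low-count filter, only the compared groups in the fit, a block for replicate number, a minimum change of 2-fold, an estimated inter-gene correlation, and leaving out each library in turn. With 1 library left out, an arm kept 2 libraries. A correction for GC content and length by splines, and library size alone for gene lists, were added after the data were seen. Transcript GC content and length were known for 90.3% of tested genes in HuCCT1, 89.4% in OCUG-1 and 87.7% in the joint fit. In simulated data the correction lowered a planted slope of 0.503 log2 per 10 GC points to 0.0164. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.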

Results

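RNA sequencing measured gene expression in 2 human biliary tract cancer cell lines grown in culture. HuCCT1 comes from an intrahepatic cholangiocarcinoma and was kept in RPMI medium, and OCUG-1 comes from a gallbladder cancer and was kept in DMEM. Each line was exposed for 72 h to 1 of 4 arms: vehicle (DMSO, at most 0.1%), sorafenib at 1.25 µM, sorafenib at 10 µM, or a combination of 1.25 µM sorafenib with 1 µM IACS-010759. Sorafenib inhibits several kinases, among them RAF and the VEGF receptors, and IACS-010759 inhibits mitochondrial complex I. Each arm had 3 libraries from separate biological replicates, 24 libraries in all. No arm held IACS-010759 alone, so its effect was measured only on top of 1.25 µM sorafenib. Cell line and medium differed together and each line is a single case.

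The total count per library was 18238834 to 30693736 in HuCCT1 and 14388855 to 24019011 in OCUG-1. Testing covered 19576 genes in HuCCT1 and 20511 in OCUG-1, and the biological coefficient of variation between replicates was 0.137 and 0.131. The first principal component held 27.9% of the variance in HuCCT1 and 69.0% in OCUG-1. In OCUG-1 it set the 6 libraries of the 10 µM and combination arms apart from the other libraries. Biliary epithelial markers, such as the keratins KRT7 and KRT8, were present above 10 CPM for 11 of 14 genes in both lines, with maxima of 4803 CPM for KRT7 in HuCCT1 and 2323 CPM for KRT8 in OCUG-1. No endothelial or immune marker exceeded 10 CPM in either line (maxima 3.81 CPM for ESAM and 2.71 CPM for CD14 in HuCCT1, 2.83 CPM for PECAM1 and 3.18 CPM for CD14 in OCUG-1). Among fibroblast markers the highest was COL1A1, at 23.3 CPM in HuCCT1 and 60.0 CPM in OCUG-1. Among hepatocyte markers the highest were SERPINA1 at 191 CPM in HuCCT1 and FGB at 38.8 CPM in OCUG-1.

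**Figure D1:**
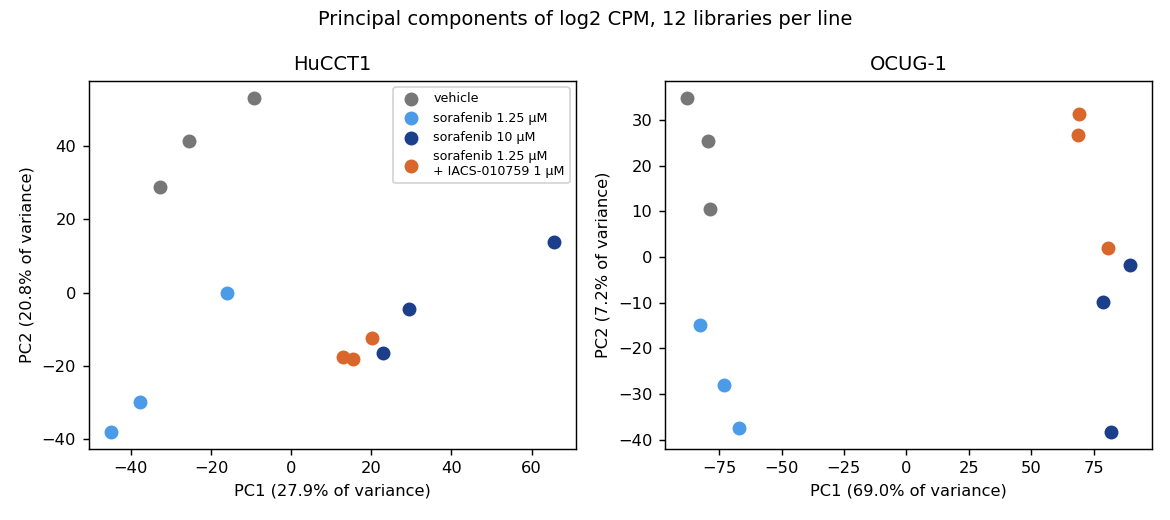
Principal components of log CPM values, 1 panel per cell line; each point is a library, coloured by arm, and the axes give the first and second components with their shares of the variance. The first component holds 27.9% in HuCCT1 and 69.0% in OCUG-1, where the 10 µM and combination libraries lie apart from the vehicle and 1.25 µM libraries.

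The first comparison asked how HuCCT1 responded to 1.25 µM sorafenib (3 libraries against 3 vehicle libraries). Genes of cell division were higher after treatment. In the mitosis list 20 of 21 genes rose (20 adjusted over the list alone), among them AURKB, a kinase of the chromosomal passenger complex, by 1.34 ± 0.14 (log2 fold change ± SE) and BUB1B, a spindle checkpoint kinase, by 1.23 ± 0.15. In the DNA replication list 19 of 22 genes rose (20 adjusted over the list alone), with the transcription factor E2F1 up by 1.23 ± 0.09 and the replicative helicase subunit MCM5 up by 1.05 ± 0.09. TXNIP, an inhibitor of thioredoxin and of glucose uptake, fell from 539.6 ± 84.1 CPM (SD) to 126 ± 17.0 CPM, a log2 fold change of -2.10 ± 0.18 (adjusted p = 8.28e-06). Median log2 fold changes were 0.96 for mitosis (adjusted p = 2.07e-22, and 0.174 with an estimated correlation) and 0.94 for DNA replication (adjusted p = 4.60e-31, and 0.0950 with an estimated correlation).

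Genes of mitochondrial respiration also rose in HuCCT1 at 1.25 µM. Among nuclear genes for subunits of oxidative phosphorylation, 42 of 78 rose (47 adjusted over the list alone), with a median of 0.33 (adjusted p = 2.59e-11, and 0.243 with an estimated correlation). Examples were the complex I subunit NDUFA2 (1.04 ± 0.14), the ATP synthase subunit ATP5MC1 (0.84 ± 0.12) and the cytochrome oxidase subunit COX7A2 (0.59 ± 0.10). By complex, 15 of 37 complex I genes, 16 of 24 genes of complexes II to IV and 11 of 17 ATP synthase genes rose (18, 18 and 11 adjusted over the list alone). All 3 calls were lost with an estimated correlation (adjusted p = 0.477, 0.135 and 0.243). Of mRNAs encoded in mitochondrial DNA, 7 of 13 rose (9 adjusted over the list alone; median 0.85, adjusted p = 2.22e-05, and 0.632 with an estimated correlation). The share of counts from the mitochondrial genome was 17.9% ± 4.83 (SD, n = 3) in these libraries and 11% ± 3.56 in vehicle. Replicate 3 had the lowest share in both arms (12.5% and 7.08%, against 21.8% and 19.4% in 1.25 µM replicates 1 and 2, and 11.8% and 14.1% in vehicle replicates 1 and 2), and in the 10 µM arm (8.32%, against 9.72% and 11.6%). In these 3 arms replicate 3 also differed most from the others, with a chi-square per degree of freedom of 31.9 to 59.0 against 6.08 to 13.5 between replicates 1 and 2. The list median was 0.60 without vehicle replicate 3 and 1.09 without 1.25 µM replicate 3, 0.63 without 1.25 µM replicate 1, and 0.85 with a block for replicate number, and it stayed called in each. The mitochondrial ribosome list had 28 of 77 genes up (30 up and 2 down adjusted over the list alone; median 0.23, adjusted p = 2.64e-06, and 0.135 with an estimated correlation). Cholesterol genes rose for 11 of 24 members (13 adjusted over the list alone), with EBP, a sterol isomerase, up by 1.01 ± 0.19 and INSIG1, a sterol-regulated inhibitor of SREBP processing, up by 0.69 ± 0.10 (list median 0.43, adjusted p = 9.10e-06, and 0.632 with an estimated correlation). In the integrated stress response list, 11 of 30 genes fell and 1 rose (16 and 1 adjusted over the list alone), with the tRNA export receptor XPOT at -0.77 ± 0.15 and the tryptophanyl-tRNA synthetase WARS1 at -0.90 ± 0.18 (list median -0.44, adjusted p = 3.01e-04, and 0.657 with an estimated correlation).

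Over all genes, 1953 rose and 1663 fell in HuCCT1 at 1.25 µM, 3616 of 19576 tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 683 changed by at least 2-fold. Among genes named by rank, the largest rises included the centromere chaperone HJURP (1.61 ± 0.16), the PCNA-binding factor PCLAF (1.6 ± 0.22) and ARHGAP33 (1.5 ± 0.21). The largest falls after TXNIP were TNFRSF11B, which encodes the decoy receptor osteoprotegerin (-1.66 ± 0.17), the citrate transporter SLC13A5 (-1.52 ± 0.17), the histone gene H2BC21 (-1.51 ± 0.13) and KRCC1 (-1.5 ± 0.23). The count of changed genes was 2090 without vehicle replicate 1, 2361 without vehicle replicate 3, 1926 without 1.25 µM replicate 1 and 1710 without 1.25 µM replicate 2. Scaling by library size alone moved the median of all genes by -0.145 and the share of changed genes that were higher from 54.0% to 26.7%, so directions here are relative to the bulk of genes.

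**Figure D2:**
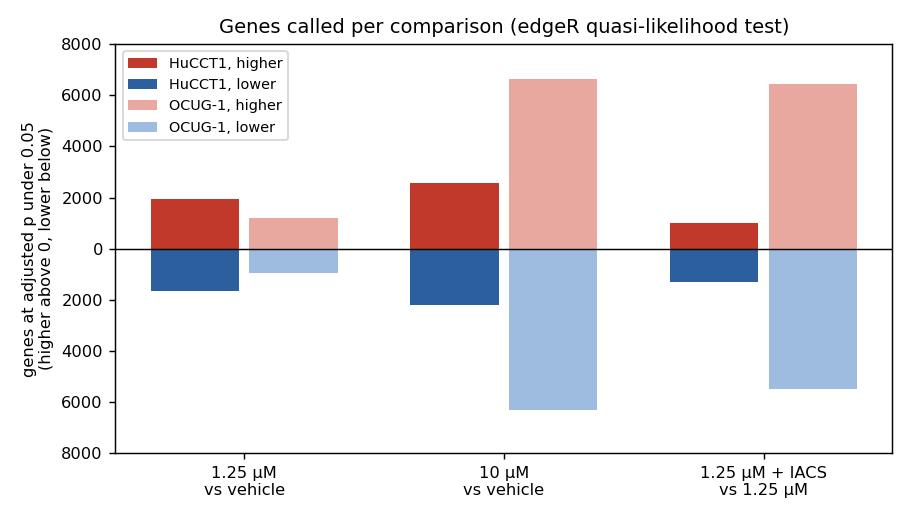
Number of genes that passed the test in each of the 3 main comparisons, as bars above 0 for genes that rose and below 0 for genes that fell, with the cell lines side by side. HuCCT1 has 3616, 4747 and 2276 changed genes and OCUG-1 has 2160, 12943 and 11914.

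At 10 µM sorafenib against vehicle, the comparison asked what the higher dose changed in HuCCT1 (3 libraries against 3). Interferon response genes were lower: 21 of 23 fell (22 adjusted over the list alone), with a median of -1.04 (adjusted p = 1.04e-23, and 0.218 with an estimated correlation). IFI6, an interferon-induced mitochondrial protein, fell from 449 ± 70.0 to 92.7 ± 33.2 CPM (-2.27 ± 0.24), and ISG15, a ubiquitin-like modifier, had a log2 fold change of -1.92 ± 0.24. Mitosis genes rose for 20 of 21 members (20 adjusted over the list alone; median 1.02, adjusted p = 4.16e-18, and 0.309 with an estimated correlation), such as the checkpoint kinase TTK (1.73 ± 0.15) and CDK1, the main mitotic cyclin-dependent kinase (1.59 ± 0.16). DNA replication genes rose for 16 of 22 members (16 adjusted over the list alone; median 0.72, adjusted p = 4.89e-10, and 0.309 with an estimated correlation). By rank, the retinol transporter gene STRA6 fell most, from 48.9 ± 8.11 to 5.00 ± 1.43 CPM (-3.27 ± 0.21), followed by H2BC21 (-3.13 ± 0.15), the antiviral GTPase gene MX2 (-2.33 ± 0.24), TXNIP (-2.30 ± 0.18) and RARRES1 (-2.29 ± 0.23). The largest rises were the pentraxin PTX3 (2.25 ± 0.36), the nucleosome-binding protein HMGN5 (2.23 ± 0.21), the cytokine LTB (2.07 ± 0.31), SERPINB7 (1.97 ± 0.22) and C1orf21 (1.92 ± 0.16). In total 2554 genes rose and 2193 fell, 4747 of 19576, of which 1264 changed by at least 2-fold.

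Smaller groups moved in HuCCT1 at 10 µM as well. Cholesterol genes rose for 9 of 24 members (10 adjusted over the list alone), including the sterol transfer protein gene STARD4 (0.97 ± 0.09). The p53 targets rose for 5 of 15 (7 up and 1 down adjusted over the list alone), including the death receptor FAS (1.33 ± 0.14) and the p53 ubiquitin ligase MDM2 (0.73 ± 0.10). In the NF-kB list 6 of 15 genes fell and 1 rose (8 and 2 adjusted over the list alone), with the iron-siderophore binder LCN2 at -1.88 ± 0.14 and the cytokine IL6 at -1.02 ± 0.14. Of the mitochondrial biogenesis regulators 5 of 11 fell and 1 rose (5 and 2 adjusted over the list alone), with the mitochondrial DNA helicase TWNK at -1.02 ± 0.09. Of the 21 genes of the tricarboxylic acid (TCA) cycle and pyruvate entry 4 rose (4 adjusted over the list alone), with isocitrate dehydrogenase IDH2 at 1.00 ± 0.12. The list medians were 0.32 (cholesterol, adjusted p = 0.00372), 0.39 (p53, 0.0264), -0.49 (NF-kB, 0.0119), -0.34 (biogenesis, 0.0264) and 0.14 (TCA, 0.0264). With an estimated correlation the adjusted p values were 0.802, 0.309, 0.674, 0.309 and 0.703. Each of these calls also ended when single libraries were left out. Without vehicle replicate 1, adjusted p was 0.058 for TCA (median 0.09), cholesterol (0.17) and p53 (0.36). Without vehicle replicate 2, TCA had a median of 0.08 and adjusted p = 0.0982. Without vehicle replicate 3, biogenesis had -0.19 and 0.0742. Without 10 µM replicate 1, biogenesis had -0.29 (adjusted p = 0.0558) and NF-kB -0.36 (0.055). Without 10 µM replicate 2, adjusted p was 0.0542 for biogenesis (-0.20), TCA (0.14) and cholesterol (0.21). Without 10 µM replicate 3, TCA had 0.12 (0.0631) and p53 0.26 (0.0597).

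Adding IACS-010759 to 1.25 µM sorafenib asked what inhibition of complex I changed on top of the low dose (3 combination libraries against 3 with 1.25 µM sorafenib alone). In HuCCT1 all 23 tested interferon response genes fell (23 adjusted over the list alone), with a median of -2.26. The call held with an estimated correlation (adjusted p = 1.33e-114 and 0.00146). RSAD2, which encodes the antiviral enzyme viperin, went from 38.7 ± 3.40 to 2.51 ± 0.531 CPM (-3.93 ± 0.22), and its neighbour CMPK2, a mitochondrial nucleotide kinase, had -3.58 ± 0.37. MX2 fell from 205 ± 15.4 to 17.5 ± 3.06 CPM (-3.55 ± 0.26), the chemokine CXCL10 by 3.48 ± 0.27 on the log2 scale and IFI6 from 458 ± 82.7 to 53.3 ± 7.90 CPM (-3.10 ± 0.25). At 1.25 µM alone against vehicle the same list had a median of 0.15 and was not called (adjusted p = 0.226). The largest rises by rank were in CDK15 (1.44 ± 0.20), the collagenase MMP1 (1.41 ± 0.18), the adaptor GRB7 (1.38 ± 0.21), ZNF488 (1.29 ± 0.26) and SYT17 (1.26 ± 0.19).

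In the same comparison other HuCCT1 groups moved less. NF-kB genes fell for 9 of 15 members and rose for 2 (10 and 3 adjusted over the list alone), with IL6 at -1.14 ± 0.14 and the chemokine CXCL2 at -1.24 ± 0.18. DNA replication genes fell for 10 of 22 (12 adjusted over the list alone), with MCM5 at -0.85 ± 0.09, while the mitosis list was not called (median 0.07, adjusted p = 0.217). mRNAs from mitochondrial DNA fell for 6 of 13 (11 adjusted over the list alone). The mitochondrial share of counts was 11.4% ± 1.08 (SD, n = 3) against 17.9% ± 4.83 without IACS-010759. The groups overlap: 1.25 µM replicate 3 was at 12.5% and combination replicate 1 at 12.6%, while 1.25 µM replicates 1 and 2 were at 21.8% and 19.4%. Vehicle libraries were at 11% ± 3.56, so the combination was near vehicle and the fall is relative to the raised 1.25 µM arm. The median of these mRNAs was -0.59 without 1.25 µM replicate 1, -0.79 without replicate 2 and -1.02 without replicate 3, and the list stayed called in each. Of the integrated stress response list 6 of 30 fell (7 adjusted over the list alone), with the glutathione-degrading enzyme CHAC1 at -1.42 ± 0.15 and the amino acid transporter SLC7A5 at -0.73 ± 0.10. Of hypoxia response genes outside glycolysis 5 of 18 rose (7 adjusted over the list alone), such as the mitophagy receptor BNIP3L (0.54 ± 0.09) and the MYC antagonist MXI1 (0.62 ± 0.11). The list medians were -0.58 (NF-kB, adjusted p = 8.15e-06), -0.36 (DNA replication, 3.51e-06), -0.80 (mitochondrial DNA, 5.41e-07), -0.23 (stress response, 6.12e-04) and 0.26 (hypoxia, 0.0111). With an estimated correlation the adjusted p values were 0.379, 0.421, 0.421, 0.652 and 0.317. The mitochondrial ribosome list had 12 of 77 genes down and 1 up (14 and 1 adjusted over the list alone) with a median of -0.17 (adjusted p = 0.00156, and 0.421 with an estimated correlation). Its median was 0.01 and its call was lost with scaling by library size alone (adjusted p = 0.0556). In total 990 genes rose and 1286 fell, 2276 of 19576, and 516 changed by at least 2-fold. The total was 1097 without 1.25 µM replicate 1, 877 without 1.25 µM replicate 2, and 982, 1053 and 959 without combination replicates 1, 2 and 3. It was 3474 with only the compared groups in the fit. Scaling by library size alone moved the median of all genes by 0.187 and the share that was higher from 43.5% to 82.4%.

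**Figure D3:**
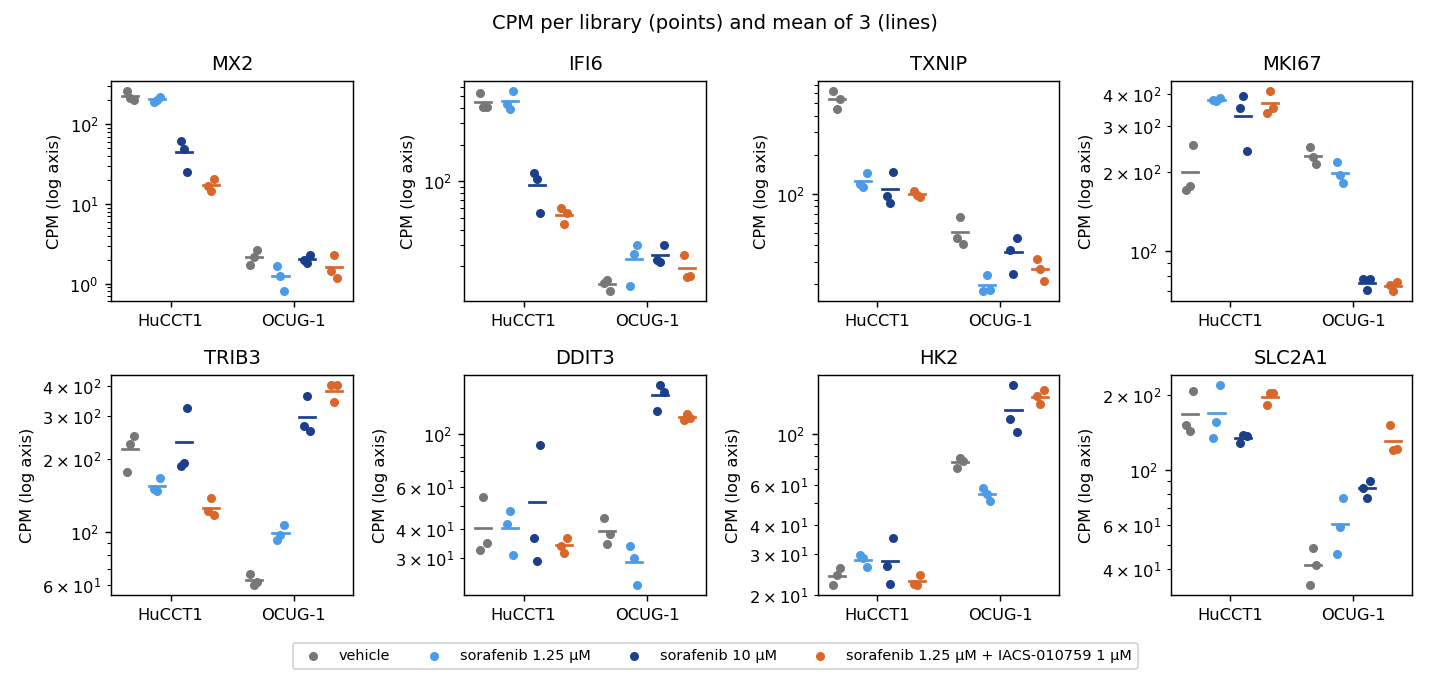
CPM per library on a log axis for MX2, IFI6, TXNIP, MKI67, TRIB3, DDIT3, HK2 and SLC2A1, by arm and cell line; points are the 3 libraries of an arm and bars their mean. In HuCCT1 the MX2 mean goes from 205 CPM at 1.25 µM sorafenib to 17.5 CPM with IACS-010759 added.

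In OCUG-1, the comparison of 1.25 µM sorafenib with vehicle asked the same low-dose question (3 libraries against 3). Output genes of the MAPK pathway were higher: 10 of 17 rose (14 adjusted over the list alone), with a median of 0.65. The call held with an estimated correlation (adjusted p = 3.63e-20 and 0.00177). The ETS factors ETV5 (1.63 ± 0.11) and ETV4 (1.35 ± 0.12), PHLDA1 (1.20 ± 0.09) and SPRED1, an inhibitor of RAS to RAF signalling (0.97 ± 0.14), were among them. Nuclear genes of oxidative phosphorylation rose for 34 of 78 members (51 up and 1 down adjusted over the list alone; median 0.35, adjusted p = 3.73e-19), with COX7A2 at 0.89 ± 0.11 and the cytochrome oxidase-associated subunit NDUFA4 at 0.69 ± 0.11. That call held with an estimated correlation (adjusted p = 0.0183). So did those of complex I (16 of 37 up, 22 up and 1 down adjusted over the list alone, adjusted p = 0.0267) and complexes II to IV (14 of 24, 19 adjusted over the list alone, adjusted p = 0.0183). ATP synthase (4 of 17, 12 adjusted over the list alone) had adjusted p = 0.0519 with an estimated correlation. The mitochondrial ribosome (27 of 77 up, 42 up and 3 down adjusted over the list alone; median 0.31) held with adjusted p = 0.0124. Hypoxia response genes outside glycolysis (9 of 18, 10 adjusted over the list alone; median 0.41) held with adjusted p = 0.0243. Among the latter were the secreted lipase inhibitor ANGPTL4, from 3.74 ± 0.371 to 22.1 ± 3.98 CPM (2.56 ± 0.18), and the collagen prolyl hydroxylase P4HA2 (0.57 ± 0.10).

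Among genes named by rank in OCUG-1 at 1.25 µM, the fibrinogen chains FGA (from 61.2 ± 7.67 to 13.8 ± 2.62 CPM, -2.15 ± 0.16) and FGB (-1.82 ± 0.14) fell, as did complement C4A (-1.82 ± 0.21), whose reads are hard to tell from those of C4B. Among hepatocyte markers, FGB and CYP3A4 fell, 2 of 6 (2 adjusted over the list alone; median -0.85, adjusted p = 8.28e-06, and 0.0183 with an estimated correlation). The hepatocyte list was low in OCUG-1: over all 12 libraries 1 of its 10 members, FGB, averaged above 10 CPM, and CYP3A4 averaged 0.470 CPM. H2BC21 had -1.99 ± 0.41, and TXNIP had -1.36 ± 0.23. The largest rises by rank after ANGPTL4 were PRSS2, a trypsinogen with close paralogs (2.22 ± 0.21), MMP1 (1.74 ± 0.17), ETV5 and the ectonucleotidase NT5E (1.5 ± 0.20).

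Further lists were called in OCUG-1 at 1.25 µM and lost with an estimated correlation. Cholesterol genes rose for 11 of 24 members (13 up and 1 down adjusted over the list alone; median 0.45, adjusted p = 7.40e-08, and 0.266 with an estimated correlation). Genes of the unfolded protein response of the endoplasmic reticulum (ER) rose for 6 of 18 (8 adjusted over the list alone; median 0.42, adjusted p = 4.45e-06, and 0.284 with an estimated correlation), including the chaperone HSPA5 (0.80 ± 0.15). Glycolysis genes rose for 7 of 22 and fell for 2 (11 and 3 adjusted over the list alone; median 0.39, adjusted p = 5.95e-04, and 0.279 with an estimated correlation). TCA (3 of 21 up, 9 up and 1 down adjusted over the list alone, median 0.25), fatty acid synthesis (3 of 13, 5 adjusted over the list alone, median 0.28), fatty acid oxidation (1 of 17, 1 adjusted over the list alone, median 0.14), autophagy (3 of 24 up and 1 down, 6 and 1 adjusted over the list alone, median 0.28) and biliary markers (3 of 14 up and 2 down, 6 and 2 adjusted over the list alone, median 0.28) had adjusted p = 6.02e-04, 0.00263, 0.0158, 0.00102 and 0.0368. With an estimated correlation their adjusted p values were 0.200, 0.279, 0.145, 0.422 and 0.279. The integrated stress response (6 of 32 up and 1 down, 8 and 2 adjusted over the list alone, median 0.08, adjusted p = 0.0324, and 0.159 with an estimated correlation) had a median of -0.01 with scaling by library size alone, with adjusted p = 0.0913, and adjusted p = 0.0507 with the GC and length correction. Mitochondrial chaperones and proteases (1 of 12 up, 3 adjusted over the list alone, median 0.18), mesenchymal markers (2 of 11 up and 1 down, 4 and 1 adjusted over the list alone, median 0.22) and fibroblast markers (1 of 7 up, 1 adjusted over the list alone, median 0.49) were called with adjusted p = 0.0420, 0.0477 and 0.0420. They had adjusted p = 0.200, 0.284 and 0.284 with an estimated correlation. Their calls also ended without single libraries: without vehicle replicate 1 the median was 0.09 for mesenchymal and 0.33 for fibroblast markers, and without vehicle replicate 3 it was 0.16 for chaperones and 0.22 for mesenchymal markers. Without 1.25 µM replicate 2 it was 0.51 for fibroblast markers, and without 1.25 µM replicate 3 it was 0.13, 0.11 and 0.50 for the lists in the order named. The chaperone call also ended with library size alone (median 0.087, adjusted p = 0.0871) and with only the compared groups (0.20, 0.065), and the mesenchymal call with the GC and length correction (0.23, 0.0603) and only the compared groups (0.24, 0.0578). In total 1214 genes rose and 946 fell in OCUG-1, 2160 of 20511, and 354 changed by at least 2-fold (113 up and 241 down). The total was 839 without vehicle replicate 1, 802 without vehicle replicate 3, 653 without 1.25 µM replicate 2 and 1082 without 1.25 µM replicate 3. Scaling by library size alone moved the share that was higher from 56.2% to 28.8%.

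At 10 µM sorafenib OCUG-1 showed a far wider response (3 libraries against 3). Of 20511 genes, 6645 rose and 6298 fell, 12943 in total, and 6920 changed by at least 2-fold. With 63.1% of tested genes changed, rises and falls here are relative to the bulk of genes. The same limit holds for OCUG-1 with IACS-010759 added. Genes of the integrated stress response, which follows phosphorylation of the initiation factor eIF2α, rose for 27 of 32 members and fell for 1 (27 and 1 adjusted over the list alone; median 1.26). The call held with an estimated correlation (adjusted p = 3.72e-16 and 0.00220). The amino acid transporter subunits SLC3A2 (2.75 ± 0.12) and SLC7A5 (2.25 ± 0.10), the glycoprotein STC2 (2.59 ± 0.11), the stress sensor SESN2 (2.36 ± 0.12), TRIB3 (2.25 ± 0.13) and the transcription factor DDIT3 (1.91 ± 0.13) were among them. All 18 genes of the ER unfolded protein response rose (18 adjusted over the list alone; median 1.88, adjusted p = 3.70e-13, and 0.217 with an estimated correlation), with the ER quality-control gene HERPUD1 from 42.5 ± 6.22 to 528 ± 86.6 CPM (3.63 ± 0.18). All 21 mitosis genes fell (21 adjusted over the list alone; median -1.48, adjusted p = 1.01e-20, and 0.0594 with an estimated correlation), such as the mitotic kinesin KIF20A (-3.77 ± 0.16), CENPF (-2.33 ± 0.10) and the proliferation marker MKI67 (-1.62 ± 0.10).

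Mitochondrial genes moved in opposite directions in OCUG-1 at 10 µM. All 13 mRNAs from mitochondrial DNA fell (13 adjusted over the list alone; median -1.74, adjusted p = 1.26e-09, and 0.249 with an estimated correlation), with the cytochrome oxidase subunit MT-CO3 at -1.97 ± 0.13. The mitochondrial share of counts was 5.95% ± 0.297 (SD, n = 3) against 12.2% ± 1.26 in vehicle. Nuclear genes of the mitochondrial ribosome rose for 50 of 77 members and fell for 5 (53 and 5 adjusted over the list alone; median 0.54, adjusted p = 1.13e-05, and 0.0999 with an estimated correlation). Regulators of mitochondrial biogenesis rose for 7 of 12 and fell for 3 (7 and 3 adjusted over the list alone; median 0.44, adjusted p = 0.0251, and 0.159 with an estimated correlation), with TWNK at 2.45 ± 0.11 and the mitochondrial transcription factor TFAM at 1.85 ± 0.18. Nuclear genes of oxidative phosphorylation rose for 27 of 78 and fell for 13 and were not called as a list (median 0.09, adjusted p = 0.509), nor were glycolysis genes (7 of 22 up and 10 down, median -0.25, adjusted p = 0.463).

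Lipid synthesis genes fell in OCUG-1 at 10 µM. Fatty acid synthesis genes fell for 10 of 13 members and rose for 1 (10 and 1 adjusted over the list alone; median -0.98, adjusted p = 6.50e-05, and 0.217 with an estimated correlation), with the lipogenic regulator SREBF1 at -2.73 ± 0.16 and fatty acid synthase FASN at -2.07 ± 0.15. Cholesterol genes fell for 13 of 24 and rose for 4 (14 and 4 adjusted over the list alone; median -0.73, adjusted p = 0.00638, and 0.70 with an estimated correlation), with lanosterol synthase LSS at -2.65 ± 0.12. NRF2 targets fell for 10 of 16 and rose for 2 (10 and 3 adjusted over the list alone; median -0.66, adjusted p = 0.00323, and 0.380 with an estimated correlation), with the pentose phosphate enzyme TKT at -2.08 ± 0.15. MAPK output genes rose for 13 of 17 and fell for 2 (13 and 2 adjusted over the list alone; median 1.32, adjusted p = 1.21e-05, and 0.0594 with an estimated correlation). Hypoxia genes outside glycolysis rose for 10 of 18 and fell for 7 (10 and 7 adjusted over the list alone; median 0.45, adjusted p = 0.0251, and 0.356 with an estimated correlation). Biliary markers fell for 7 of 14 and rose for 4 (7 and 4 adjusted over the list alone; median -0.54, adjusted p = 0.0269, and 0.253 with an estimated correlation), with keratin KRT19 at -1.92 ± 0.12. The call ended without 10 µM replicate 2 (median -0.40, adjusted p = 0.05). Autophagy and lysosome genes rose for 16 of 24 and fell for 3 (16 and 3 adjusted over the list alone; median 0.64, adjusted p = 0.0248, and 0.816 with an estimated correlation). This call ended without 10 µM replicate 3 (median 0.54, adjusted p = 0.0582). Hepatocyte markers fell for 4 of 6 and rose for 2 (4 and 2 adjusted over the list alone; median -2.54, adjusted p = 0.0471, and 0.217 with an estimated correlation). That call ended with any 1 library left out: the median was -1.22, -1.31 and -1.53 without vehicle replicates 1, 2 and 3, and -2.43, -1.29 and -1.45 without 10 µM replicates 1, 2 and 3. It also ended with a block for replicate number (median -2.52, adjusted p = 0.0521). Without a low-count filter the list median was 1.27 and the list was not called (adjusted p = 0.668). That fit also held members with counts too low for the filter, such as TTR, which averaged 0.056 CPM over the OCUG-1 libraries. The 2 medians therefore cover different members. The 5 tested genes of sorafenib's target kinases were not called as a list (3 up and 2 down, median 0.46, adjusted p = 0.863).

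By rank, the largest rises in OCUG-1 at 10 µM included HSPA6, an inducible HSP70 chaperone, from 1.97 ± 0.715 to 716 ± 324 CPM (8.51 ± 0.52), the cornified-envelope gene SPRR2D (6.48 ± 0.33), the anticoagulant receptor THBD (6.25 ± 0.27) and the cytokine receptor IL7R (5.48 ± 0.23). HSPA6 has a close relative in HSPA7, so reads can be shared. GPA33 was at 0.0610 ± 0.0617 CPM in vehicle and 12.4 ± 7.76 CPM at 10 µM. The largest falls were CYP4F8, a fatty acid hydroxylase (from 80.5 ± 10.9 to 0.453 ± 0.199 CPM, -7.47 ± 0.23), FGA (-5.60 ± 0.20), the helicase PIF1 (-4.56 ± 0.24), the carnosine synthase CARNS1 (-4.54 ± 0.25) and the interferon gene IFNE (-4.47 ± 0.54). HK2, a hexokinase, had 0.75 ± 0.13 (adjusted p = 8.56e-05), the glucose transporter SLC2A1 1.02 ± 0.16 (4.15e-05) and the stress cytokine GDF15 0.23 ± 0.12, which did not pass the test (adjusted p = 0.112).

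**Figure D4:**
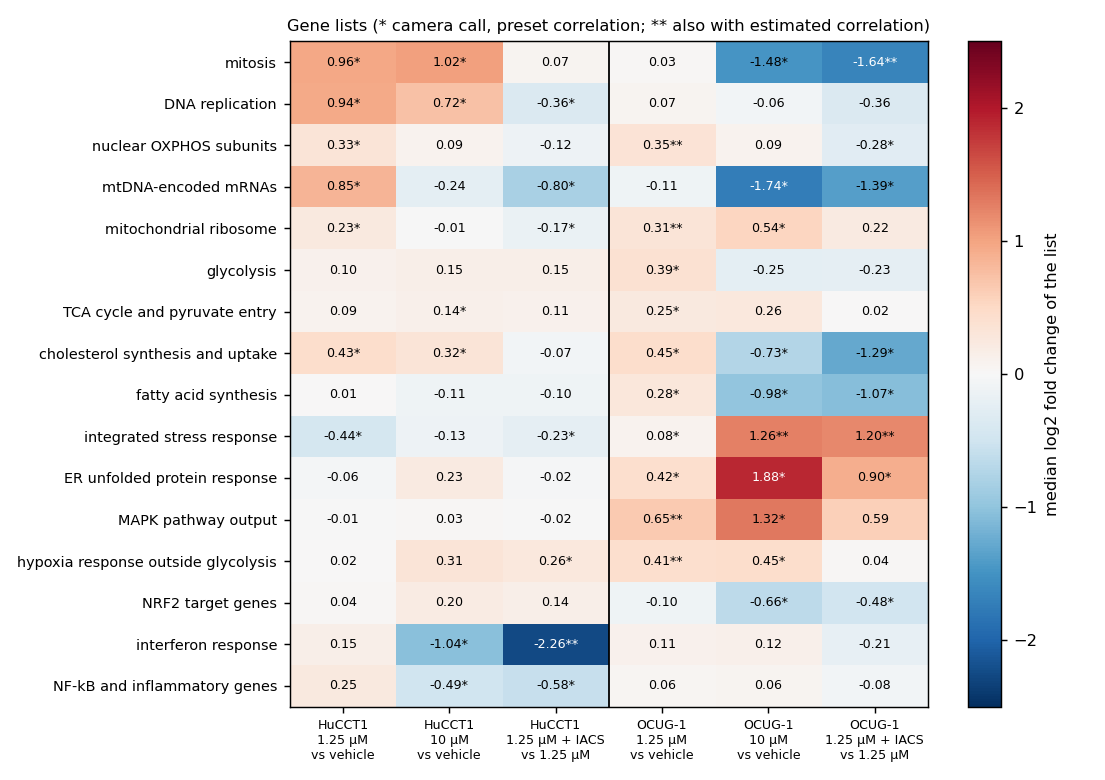
Heat map of the median log2 fold change of 16 gene lists in the 3 main comparisons of each line; 1 star marks lists called with the preset correlation and 2 stars those also called with an estimated correlation. Mitosis genes have medians of 1.02 in HuCCT1 and -1.48 in OCUG-1 at 10 µM sorafenib, and interferon response genes have -2.26 in HuCCT1 with IACS-010759 added.

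Adding IACS-010759 to 1.25 µM sorafenib in OCUG-1 changed 11914 of 20511 genes (6434 rose and 5480 fell, 5897 by at least 2-fold; 3 libraries against 3). Integrated stress response genes rose for 28 of 32 members and fell for 2 (28 and 2 adjusted over the list alone; median 1.20). The call held with an estimated correlation (adjusted p = 1.44e-19 and 6.06e-04). SESN2 (2.71 ± 0.13), SLC3A2 (2.65 ± 0.11), SLC7A5 (2.61 ± 0.10), STC2 (2.55 ± 0.11) and DDIT3 (2.02 ± 0.14) were among the members that rose. All 21 mitosis genes fell (21 adjusted over the list alone; median -1.64), with DNA topoisomerase TOP2A at -2.64 ± 0.12. The call held with an estimated correlation (adjusted p = 4.90e-31 and 0.0373). Biogenesis regulators rose for 9 of 12 and fell for 1 (9 and 1 adjusted over the list alone; median 0.90), and the call held (adjusted p = 5.36e-04, and 0.0373 with an estimated correlation), with TWNK at 2.46 ± 0.11, PPRC1 at 1.49 ± 0.11 and TFAM at 1.30 ± 0.17. All 13 mRNAs from mitochondrial DNA fell (13 adjusted over the list alone; median -1.39, adjusted p = 3.15e-09, and 0.293 with an estimated correlation). The mitochondrial share of counts was 5.43% ± 0.926 (SD, n = 3) against 11.1% ± 1.89 without IACS-010759.

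Metabolic groups also fell in OCUG-1 when IACS-010759 was added. Nuclear genes of oxidative phosphorylation fell for 40 of 78 members and rose for 5 (40 and 5 adjusted over the list alone; median -0.28, adjusted p = 0.00867, and 0.428 with an estimated correlation), with COX7B at -0.87 ± 0.11. Cholesterol genes fell for 19 of 24 and rose for 1 (19 and 1 adjusted over the list alone; median -1.29, adjusted p = 2.28e-11, and 0.211 with an estimated correlation), with LSS at -2.23 ± 0.12. Fatty acid synthesis genes fell for 10 of 13 (10 adjusted over the list alone; median -1.07, adjusted p = 1.55e-07, and 0.176 with an estimated correlation), with the stearoyl desaturase SCD at -1.81 ± 0.16. Fatty acid oxidation genes fell for 10 of 17 and rose for 1 (10 and 1 adjusted over the list alone; median -0.40, adjusted p = 0.0119, and 0.176 with an estimated correlation). ER stress genes rose for 14 of 18 (14 adjusted over the list alone; median 0.90, adjusted p = 8.24e-06, and 0.428 with an estimated correlation), with HERPUD1 at 3.17 ± 0.18. Biliary markers (8 of 14 down and 3 up, 8 and 3 adjusted over the list alone, median -0.74), fibroblast markers (6 of 7 down, 7 adjusted over the list alone, median -1.41) and NRF2 targets (10 of 16 down and 3 up, 10 and 3 adjusted over the list alone, median -0.48) were called with adjusted p = 0.00120, 0.00128 and 0.0381. They had adjusted p = 0.176, 0.176 and 0.459 with an estimated correlation. The hexokinase gene HK2 rose by 1.40 ± 0.14, SLC2A1 by 1.11 ± 0.16, the cell cycle inhibitor CDKN1A by 1.28 ± 0.14 and GDF15 by 0.89 ± 0.12, while the lactate dehydrogenase gene LDHA had -0.63 ± 0.13. The largest changes by rank repeated HSPA6 (8.20 ± 0.54), SPRR2D (6.54 ± 0.33), THBD (5.70 ± 0.24), CYP4F8 (-7.21 ± 0.27), FGA (-5.33 ± 0.26) and PIF1 (-4.04 ± 0.24). They added the mucin MUC13 (5.24 ± 0.36), NHLH1 (5.57 ± 0.56), the nucleoside transporter SLC28A3 (-4.48 ± 0.25) and the tight junction gene CLDN2 (-3.99 ± 0.20). Scaling by library size alone moved the median of all genes by 0.151.

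The overlap of responses asked whether the higher dose and the added complex I inhibitor involved the same genes. In OCUG-1 the changes at 10 µM against vehicle and those from adding IACS-010759, which share no libraries, had a Spearman correlation of 0.81 and a Pearson correlation of 0.84 across 20511 genes, where genes are not independent replicates. Of 9235 genes that passed in both, 98.1% moved in the same direction: 4895 rose in both (2084 expected from the separate counts) and 4165 fell in both (1683 expected). In HuCCT1 the same pair had a Spearman correlation of 0.32, and 1046 genes passed in both, 90.5% in the same direction. Simulated unchanged groups gave 0.00244 for OCUG-1 and -8.8e-04 for HuCCT1. The simulated libraries were drawn independently, so the lack of correlation there follows from the design. It does not cover factors common to several real libraries. Between lines the Spearman correlations were 0.06 at 1.25 µM, -0.01 at 10 µM and -0.09 for added IACS-010759. At 1.25 µM 520 genes passed in both lines, with 265 up in both (127 expected), 113 down in both (75.2 expected) and 142 in opposite directions (196 expected). At 10 µM 3068 passed in both, with 817 up (785 expected), 724 down (620.2 expected) and 1527 opposite (1397 expected). For added IACS-010759 1469 passed in both, with 210 up (288 expected), 295 down (326 expected) and 964 opposite (629 expected).

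**Figure D5:**
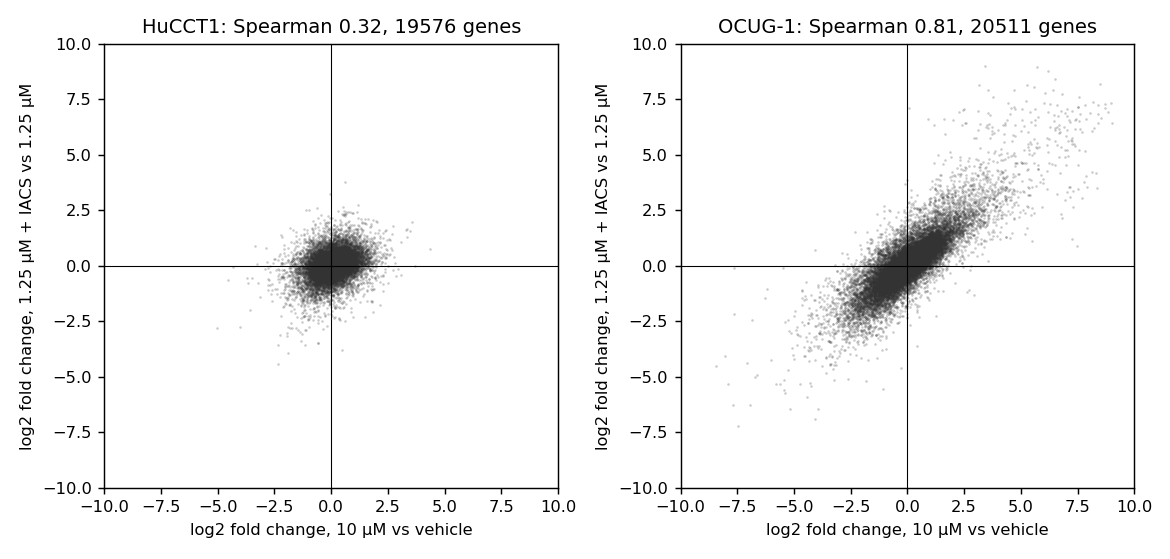
Log2 fold change of each gene at 10 µM sorafenib against vehicle (x axis) and with IACS-010759 added to 1.25 µM sorafenib (y axis), 1 panel per line, 1 point per gene. The Spearman correlation is 0.32 in HuCCT1 and 0.81 in OCUG-1.

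Comparisons that share libraries were set beside simulated unchanged groups. In HuCCT1 the changes at 1.25 µM and at 10 µM, both against the same vehicle libraries, had a covariance of 0.152 (0.0449 in simulated groups), with 817 genes up in both (255 expected) and 553 down in both (186 expected). In OCUG-1 the covariance was 0.199 (0.0462 in simulated groups), with 769 up (393 expected) and 619 down (290 expected). The changes at 1.25 µM and from adding IACS-010759, which share the 1.25 µM libraries with opposite sign, had covariances of -0.122 in HuCCT1 (-0.0487 simulated) and -0.145 in OCUG-1 (-0.0458 simulated). Shared libraries contribute to each overlap, and with 3 libraries per arm they cannot be split into 2 sets of at least 2 to remove it.

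The 10 µM and 1.25 µM doses were also compared directly (3 libraries against 3). In HuCCT1 2827 genes rose and 2691 fell, 5518 of 19576, and 1137 changed by at least 2-fold. Interferon response genes fell for 21 of 23 members (22 adjusted over the list alone; median -1.39, adjusted p = 1.91e-30, and 0.0996 with an estimated correlation), with ISG15 at -2.52 ± 0.24 and RSAD2 at -2.23 ± 0.20, and ABI3BP rose by 2.58 ± 0.28. All 13 mRNAs from mitochondrial DNA fell (13 adjusted over the list alone; median -1.10, adjusted p = 1.09e-06, and 0.494 with an estimated correlation), with mitochondrial shares of 9.88% ± 1.63 (SD, n = 3) and 17.9% ± 4.83. The median of these mRNAs was -0.87, -1.06 and -1.33 without 1.25 µM replicates 1, 2 and 3, and the list stayed called in each. The mitochondrial share in HuCCT1 vehicle libraries was 11% ± 3.56, near that at 10 µM. Nuclear genes of oxidative phosphorylation fell for 34 of 78 and rose for 2 (40 and 3 adjusted over the list alone; median -0.31, adjusted p = 1.87e-05, and 0.494 with an estimated correlation). For 10 µM against vehicle this list had a median of 0.09 and was not called by camera (adjusted p = 0.285), so its fall is relative to the raised 1.25 µM arm. The HuCCT1 total was 3567 without 1.25 µM replicate 1 and 3472 without 1.25 µM replicate 2, and scaling by library size alone moved the median of all genes by 0.180 and the share that was higher from 51.2% to 77.5%. In OCUG-1 6472 genes rose and 5942 fell, 12414 of 20511, and 6296 changed by at least 2-fold. Integrated stress response genes rose for 27 of 32 and fell for 1 (27 and 1 adjusted over the list alone; median 1.19), and the call held with an estimated correlation (adjusted p = 2.91e-15 and 0.00322). HSPA6 rose by 9.42 ± 0.55 and CYP4F8 had -6.03 ± 0.24. PRSS2, higher at 1.25 µM than in vehicle, was at 0.999 ± 0.0942 CPM at 10 µM against 23.6 ± 4.06 CPM at 1.25 µM (-4.57 ± 0.25). Scaling by library size alone moved the median of all genes by 0.121 in OCUG-1.

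The combination was compared with vehicle to measure both drugs together (3 libraries against 3). In HuCCT1 1945 genes rose and 1986 fell, 3931 of 19576, and 1002 changed by at least 2-fold (608 up and 394 down). All 23 interferon response genes fell (23 adjusted over the list alone; median -2.0), which held with an estimated correlation (adjusted p = 1.44e-72 and 0.00822), with MX2 at -3.69 ± 0.26, RSAD2 at -3.63 ± 0.22 and IFI44L at -3.33 ± 0.25. Mitosis genes rose for 20 of 21 (21 adjusted over the list alone; median 1.13, adjusted p = 1.35e-24, and 0.166 with an estimated correlation). By rank ARHGAP33 (2.07 ± 0.21), the MAX partner MXD3 (1.98 ± 0.16) and ATP8B3 (1.90 ± 0.33) rose most. Integrated stress response genes fell for 17 of 30 (23 adjusted over the list alone; median -0.65, adjusted p = 6.02e-11, and 0.257 with an estimated correlation). The HuCCT1 total was 2500 without vehicle replicate 1, and 2353, 2603 and 2342 without combination replicates 1, 2 and 3. In OCUG-1 6452 genes rose and 5761 fell, 12213 of 20511, and 6140 changed by at least 2-fold (3062 up and 3078 down). Integrated stress response (29 of 32 up and 2 down, 29 and 2 adjusted over the list alone, median 1.23), MAPK output (13 of 17 up and 1 down, 14 and 1 adjusted over the list alone, median 1.19) and mitosis (21 of 21 down, 21 adjusted over the list alone, median -1.59) were called, and held with an estimated correlation (adjusted p = 3.99e-04, 0.0281 and 0.0393). THBD rose by 6.86 ± 0.27, and the stromelysin MMP3 was at 0.0610 ± 0.0617 CPM in vehicle and 10.4 ± 1.85 CPM in the combination.

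Whether the lines responded differently was tested as the difference of log2 fold changes, OCUG-1 minus HuCCT1, in a fit of all 24 libraries (22944 genes). The difference passed the test for 2214 genes at 1.25 µM (1138 higher and 1076 lower, and 900 by at least 2-fold, 337 higher and 563 lower), 10047 at 10 µM (6476) and 8895 for added IACS-010759 (5440). At 1.25 µM the integrin ITGB3 differed by 3.04 ± 0.40 (-1.71 in HuCCT1 and 1.29 in OCUG-1) and EID3 by -2.61 ± 0.44 (1.20 and -1.44). DNA replication genes were lower in OCUG-1 relative to HuCCT1 (15 of 22, 18 adjusted over the list alone, median difference -0.75), MAPK output genes higher (9 of 18 higher and 1 lower, 9 and 1 adjusted over the list alone, 0.56) and hypoxia genes higher (7 of 18, 9 adjusted over the list alone, 0.55). These 3 calls held with an estimated correlation (adjusted p = 0.0280, 0.0216 and 0.0280). At 10 µM THBD differed by 7.18 ± 0.33 (-1.0 and 6.25), the lipoprotein receptor LRP1B by -5.55 ± 0.43 (1.20 and -4.32) and PIF1 by -5.73 ± 0.57 (1.10 and -4.56). All 21 mitosis genes were lower in OCUG-1 relative to HuCCT1 (21 adjusted over the list alone; median -2.59, adjusted p = 8.14e-33, and 0.0509 with an estimated correlation). For added IACS-010759, RSAD2 differed by 6.91 ± 0.44 (-3.93 in HuCCT1 and 3.09 in OCUG-1) and SLC28A3 by -5.17 ± 0.62 (0.53 and -4.48). Interferon genes were higher in OCUG-1 relative to HuCCT1 for 19 of 23 members and lower for 1 (19 and 1 adjusted over the list alone; median 1.88, adjusted p = 8.89e-15, and 0.0604 with an estimated correlation). In HuCCT1 alone all 23 of these interferon genes fell with IACS-010759 added, and in OCUG-1 alone the list was not called. The difference therefore does not show a rise of the list in OCUG-1. Biogenesis regulators were higher in the OCUG-1 response at 10 µM (7 of 12 higher and 2 lower, 7 and 2 adjusted over the list alone, median 0.63) and with added IACS-010759 (7 of 12 higher, 9 and 1 adjusted over the list alone, 0.78). Both held with an estimated correlation (adjusted p = 0.0311 and 0.00377). The count at 1.25 µM was 1461 without HuCCT1 vehicle replicate 3, 1209, 1268 and 3385 without HuCCT1 1.25 µM replicates 1, 2 and 3, 1275 and 1472 without OCUG-1 vehicle replicates 1 and 3, and 1388 and 1286 without OCUG-1 1.25 µM replicates 2 and 3.

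Without drug, the lines differed in 15682 of 22944 genes (8178 higher and 7504 lower in OCUG-1, 10485 by at least 2-fold; 3 vehicle libraries each). Cell line and medium differ together here. All 23 interferon response genes were lower in OCUG-1 (23 adjusted over the list alone; median -3.51, adjusted p = 3.48e-23). Of MAPK output genes 15 of 18 were lower and 1 higher (15 and 1 adjusted over the list alone; median -1.93, adjusted p = 1.36e-07), and 14 of 16 NRF2 targets were higher (14 adjusted over the list alone; median 1.64, adjusted p = 2.92e-08). Biliary markers were lower for 9 of 14 and higher for 3 (9 and 3 adjusted over the list alone; median -0.85, adjusted p = 1.44e-05). These 4 calls held with an estimated correlation (adjusted p = 0.0174, 0.0174, 0.0353 and 0.0174). Mitosis genes were higher for 15 of 21 (16 adjusted over the list alone; median 0.78, adjusted p = 0.0481, and 0.980 with an estimated correlation), a call that ended without HuCCT1 vehicle replicate 1 (median 0.67) or replicate 2 (0.70). The secreted phosphoprotein SPP1 was at 2146 ± 721 CPM, the ubiquitin hydrolase UCHL1 at 820.4 ± 22.4 CPM and the carboxylesterase CES1 at 349 ± 36.2 CPM in OCUG-1, and all 3 were at 0 in the HuCCT1 vehicle libraries. PHACTR3 was at 45 ± 9.64 CPM in HuCCT1 and at 0 in OCUG-1. Scaling by library size alone moved the median of all genes by 0.150.

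In GRCh38 with GENCODE 29 coordinates, MX2 (ENSG00000183486) lies on chromosome 21 from 41361943 to 41409390 and RSAD2 (ENSG00000134321) on chromosome 2 from 6865806 to 6898239. IFI6 (ENSG00000126709) lies on chromosome 1 from 27666061 to 27672218 and TXNIP (ENSG00000265972) on chromosome 1 from 145992435 to 145996600. HSPA6 (ENSG00000173110) lies on chromosome 1 from 161524540 to 161526910, CYP4F8 (ENSG00000186526) on chromosome 19 from 15615218 to 15630638 and FGA (ENSG00000171560) on chromosome 4 from 154583126 to 154590766.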

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

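The tests of differences between the lines, and the count of other ways to split the libraries for those differences, were planned; the 3 patterns weighed last were picked after the results were seen, and the test of the extra sequencing runs was chosen only after the result was seen. The responses of the lines, OCUG-1 minus HuCCT1, differed for 2214 genes at 1.25 µM sorafenib, 10047 at 10 µM and 8895 for added IACS-010759 (edgeR quasi-likelihood test of the difference). At 1.25 µM the list medians that differed were 0.55 for hypoxia genes, 0.56 for MAPK output, -0.75 for DNA replication, -0.93 for mRNAs from mitochondrial DNA, 0.41 for fatty acid oxidation, 0.55 for the integrated stress response, 0.36 for the ER unfolded protein response, -0.90 for mitosis and 0.58 for autophagy. With an estimated correlation hypoxia, MAPK output and DNA replication held, and the other 6 did not (adjusted p between 0.0999 and 0.724).

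At 10 µM the medians that differed were 0.63 for biogenesis regulators, -1.39 for mRNAs from mitochondrial DNA, 0.46 for the mitochondrial ribosome, -0.93 for cholesterol genes, -0.74 for fatty acid synthesis, 1.07 for the integrated stress response, 1.43 for the ER unfolded protein response, 0.54 for mitochondrial chaperones, 1.13 for MAPK output, -2.59 for mitosis, -0.84 for DNA replication, -0.90 for p53 targets, -0.98 for NRF2 targets, 0.44 for autophagy and 0.93 for interferon genes. For added IACS-010759 they were 0.78 for biogenesis regulators, -0.31 for nuclear oxidative phosphorylation, 0.28 for the mitochondrial ribosome, -0.57 for glycolysis, -0.83 for fatty acid oxidation, -1.19 for cholesterol genes, -0.94 for fatty acid synthesis, 1.26 for the integrated stress response, 0.97 for the ER unfolded protein response, -1.97 for mitosis, -0.93 for p53 targets, -0.81 for NRF2 targets, 1.88 for interferon genes and -1.06 for biliary markers. In both sets biogenesis regulators alone held with an estimated correlation. Some of these calls also ended under other alternatives. At 10 µM the p53 call ended with RLE factors (-0.85, adjusted p = 0.0554), library size alone (-0.84, 0.0525) and only the compared groups in the fit (-0.87, 0.0764). It also ended without HuCCT1 vehicle replicates 1 (-0.85) and 2 (-0.78), HuCCT1 10 µM replicate 3 (-0.83), OCUG-1 vehicle replicates 2 (-0.86) and 3 (-0.87), and OCUG-1 10 µM replicates 1 (-0.85) and 2 (-0.87). The call of mitochondrial chaperones ended without HuCCT1 vehicle replicate 1 (0.56), HuCCT1 10 µM replicates 1 (0.48) and 2 (0.54), OCUG-1 vehicle replicate 3 (0.51), and OCUG-1 10 µM replicates 1 (0.55) and 2 (0.54). That of autophagy ended without OCUG-1 10 µM replicate 3 (0.30, adjusted p = 0.0503). For added IACS-010759 the calls of p53 targets (-0.92, adjusted p = 0.0637) and oxidative phosphorylation (-0.30, 0.0586) ended with only the compared groups, and the latter also without HuCCT1 1.25 µM replicate 3 (-0.24, 0.0617).

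In each of the 3 differences 1 of 100 splits of the libraries, the real one, called as many genes. The highest other split gave 1431 genes at 1.25 µM, 9978 at 10 µM and 7883 for added IACS-010759. The split with 9978 genes kept the OCUG-1 arms whole and had the HuCCT1 arms exchanged, that with 7883 kept the OCUG-1 arms whole, and that with 1431 had the HuCCT1 arms exchanged and the OCUG-1 libraries mixed. A split that mixes the arms of a line moves that line's own response into the spread between replicates, which lowers the count by construction. Splits that mixed the OCUG-1 arms gave at most 860 genes at 10 µM and 87 for added IACS-010759. The splits therefore say little about a difference between the lines in any of the 3 comparisons, and chance is not excluded by them. The differences rest on the edgeR test.

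The first pattern is the fall of interferon response genes in HuCCT1 when IACS-010759 was added, with a median of -2.26. After a correction for GC content and length the median was -2.26, with an interquartile range of 1.11 over 23 genes. It was also -2.26 relative to all genes with mitochondrial genes removed and library size alone. Subtracting the median of all genes cancels any shift that moves all genes alike, so this value cannot test a composition shift. Scaling by library size alone moved the median of all genes by 0.187, far less than the fall of the list. The leave-one-out median nearest 0 was -2.22 over 6 libraries. The corrected median and the leave-one-out medians argue against GC or length bias and a single deviating library as the whole cause. An effect of complex I inhibition on interferon signalling may underlie the fall with IACS-010759 added, as a hypothesis. Without an arm of IACS-010759 alone that effect cannot be separated from an effect of the drugs together.

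The second pattern is the wide OCUG-1 response that 10 µM sorafenib and added IACS-010759 shared. After the GC and length correction the Pearson correlation of the 2 responses was 0.839, which argues against that bias as the cause. The Spearman correlations of log2 fold change with transcript length were -0.0112 and -0.00364, so no trend with length was seen. Length was that of the longest annotated transcript of a gene, and no measure of RNA integrity was examined. RNA degradation without a length trend is therefore not excluded. On the first principal component 6 libraries stood apart, whereas 4 OCUG-1 libraries had extra runs, so extra runs alone cannot explain the grouping. What links the 2 arms was not tested.

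The third pattern is the opposite direction of mitosis genes at 10 µM sorafenib. After the GC and length correction the median difference was -2.53, and the lines had medians of 1.01 in HuCCT1 (18 of 21 up) and -1.53 in OCUG-1 (21 of 21 down). The leave-one-out median of the difference nearest 0 was -2.39 over 12 libraries. These values argue against GC or length bias and a single deviating library. A difference in drug response between the lines may explain the pattern, but cell line, tissue of origin and medium differ together, and which of them matters was not tested.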

How the results depend on the processing

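The correction for GC content and length, and scaling by library size alone for gene lists, were chosen after seeing the data, and the other alternatives were planned. No named gene that was called changed sign, and no called gene list changed the direction that camera gives it, under any alternative run. Counts of changed genes stayed within 1.5 times in 14 of 14 comparisons with DESeq2, RLE factors, library size alone, no low-count filter and the GC and length correction. A block for replicate number, as if the numbers paired libraries, also left all 14 counts within 1.5 times. Asking for at least a 2-fold change, stricter by construction, left 683, 1264, 516, 1137 and 1002 genes in HuCCT1 (1.25 µM, 10 µM, added IACS-010759, 10 against 1.25 µM, combination against vehicle). It left 354, 6920, 5897, 6296 and 6140 in OCUG-1 in the same order, and 900, 6476 and 5440 for the differences between lines. With only the compared groups in the fit, HuCCT1 had 2616 changed genes at 1.25 µM (3616 in the main fit) and 3396 at 10 µM (4747). Added IACS-010759 then changed 3474 (2276 in the main fit), and the combination against vehicle 4998 (3931). The order of the HuCCT1 counts therefore depends on which groups share the fit (the cause was not tested). With 1 library left out, the counts ranged from 1710 to 4749 (HuCCT1, 1.25 µM), 877 to 3224 (HuCCT1, added IACS-010759), 3472 to 6284 (HuCCT1, 10 against 1.25 µM), 2342 to 3293 (HuCCT1, combination against vehicle), 653 to 2558 (OCUG-1, 1.25 µM) and 1209 to 3385 (difference at 1.25 µM), and in the remaining comparisons they stayed within 1.5 times.

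Gene lists depended most on whether the inter-gene correlation was preset or estimated. With an estimated correlation 26 list calls held and 139 ended. With the GC and length correction 161 calls held and 4 ended, with library size alone 160 and 5, with no low-count filter 163 and 2, with only the compared groups 160 and 5, with the block for replicate number 164 and 1 (hepatocyte markers in OCUG-1 at 10 µM), with RLE factors 164 and 1, and with 1 library left out 1158 and 60. Lists that had not been called passed in 21, 7, 55, 2, 10 and 90 cases under these alternatives in the same order, leaving out RLE factors. Nuclear oxidative phosphorylation lost its call with an estimated correlation in HuCCT1 at 1.25 µM (median 0.33), at 10 against 1.25 µM (-0.31) and for the combination against vehicle (0.26), and in OCUG-1 for added IACS-010759 (-0.28) and 10 against 1.25 µM (-0.25). Glycolysis lost its call in the same way for the HuCCT1 combination against vehicle (0.21), OCUG-1 at 1.25 µM (0.39) and OCUG-1 at 10 against 1.25 µM (-0.58). Glycolysis passed where it had not before in HuCCT1 at 10 µM with the GC and length correction (0.28), and without a filter for added IACS-010759 in HuCCT1 (0.20) and OCUG-1 (-0.25). With library size alone, oxidative phosphorylation lost its call in OCUG-1 at 10 against 1.25 µM (-0.14). The median of 4 called lists changed sign as their calls ended: the mitochondrial ribosome for added IACS-010759 in HuCCT1 (0.013) and the integrated stress response in OCUG-1 at 1.25 µM (-0.014) with library size alone, and hepatocyte markers in OCUG-1 at 10 µM (1.27) and for the combination against vehicle (0.49) with no filter. Without the filter the hepatocyte list gained members with very low counts, so its medians with and without the filter cover different members. The cause was not tested for any of the changes in this paragraph. With 1 library left out, glycolysis medians ran from -0.048 to 0.24 (HuCCT1, 1.25 µM), 0.056 to 0.27 (HuCCT1, 10 µM), 0.094 to 0.28 (HuCCT1, added IACS-010759), 0.11 to 0.38 (HuCCT1, combination against vehicle), -0.32 to -0.21 (OCUG-1, added IACS-010759) and -0.67 to -0.49 (OCUG-1, 10 against 1.25 µM), and oxidative phosphorylation medians from -0.18 to -0.035 (HuCCT1, added IACS-010759) and -0.35 to -0.24 (OCUG-1, 10 against 1.25 µM). Among calls of named genes, 451 held and 3 ended with DESeq2, 454 and 1 with RLE factors, 445 and 10 with the GC and length correction, 440 and 15 with the block, 446 and 9 with only the compared groups, 435 and 20 with no filter, 430 and 25 with library size alone, and 2630 and 280 with 1 library left out. The effect of depth on the calls was not tested.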

Other observations

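The 2 gene lists in this part, and their tests, were chosen after values had been seen, as were the splits of the libraries within a line or between the vehicle groups. HSPA6 was among the largest rises in OCUG-1, and a wider rise of heat-shock chaperone genes was tested as a hypothesis on the other members, with HSPA6 left out. Of 21 chaperone genes, 20 rose and 1 fell at 10 µM sorafenib (median 2.14), and 18 rose and 1 fell with IACS-010759 added (1.68). In both comparisons 18 rose, so a wider rise of heat-shock chaperone genes may accompany that of HSPA6. The list was called in both (adjusted p = 5.38e-21 and 1.79e-13), and neither call held with an estimated correlation (adjusted p = 0.0852 and 0.146). At 1.25 µM 2 rose and 2 fell (0.16). In HuCCT1 the medians were 0.12 at 1.25 µM and -0.06 at 10 µM, where the list was not called. With IACS-010759 added 5 of 20 fell in HuCCT1 (median -0.18), and the list was called lower (adjusted p = 0.0166), a call that was lost with an estimated correlation (adjusted p = 0.388). HSPE1, a mitochondrial chaperonin subunit, was lower in OCUG-1 at 10 µM (-0.47) and with IACS-010759 added (-0.85).

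The falls of fibrinogen and C4 genes in OCUG-1 raised the hypothesis of a wider fall of complement and acute-phase genes, tested with FGA, FGB, FGG, C4A and C4B left out. Of the 9 other members 4 fell at 1.25 µM (median -0.53), 9 at 10 µM (-1.86) and 8 with IACS-010759 added (-1.76). In both of the latter comparisons 8 fell, all members except LCN2 (0.21 with IACS-010759 added), so a wider fall of complement and acute-phase genes may accompany that of fibrinogen. The list was called in all 3 (adjusted p = 1.28e-05, 8.41e-06 and 3.19e-05), and no call held with an estimated correlation (adjusted p = 0.0998, 0.121 and 0.146). In HuCCT1 6 of 9 fell at 10 µM (-0.92) and 5 with IACS-010759 added (-0.70), with adjusted p = 0.0296 and 0.0107 with an estimated correlation. That depends on which members are left out, since with all 12 tested members the adjusted p values were 0.117 and 0.0628. At 1.25 µM 1 of the 9 rose and 3 fell, and the list was not called (-0.17, adjusted p = 0.126).

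The ratio of mRNA to rRNA counts from mitochondrial DNA was 7.73 ± 0.907 (SD, n = 3) in OCUG-1 vehicle libraries, 6.57 ± 0.364 at 1.25 µM, 1.46 ± 0.158 at 10 µM and 3.75 ± 0.172 in the combination. In HuCCT1 it was 8.51 ± 0.714, 14.2 ± 0.398, 10.3 ± 3.69 and 8.53 ± 0.232 in the same order.

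Within a line, and between the vehicle groups, 3 libraries against 3 make 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The real counts and the highest of the other splits were 3616 and 412 (HuCCT1, 1.25 µM), 4747 and 2 (HuCCT1, 10 µM) and 2160 and 1 (OCUG-1, 1.25 µM). The highest other split gave 0 genes (edgeR) beside 2276, 5518 and 3931 in HuCCT1 (added IACS-010759, 10 against 1.25 µM, combination against vehicle), 12943, 11914, 12414 and 12213 in OCUG-1 (10 µM, added IACS-010759, 10 against 1.25 µM, combination against vehicle) and 15682 between the vehicle groups.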
